A study of Rattus norvegicus with 18 samples.

How the data were processed

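RNA from the knee synovial tissue of male Lewis rats was measured on 18 single-colour (Cy3) Agilent rat arrays, with 3 arrays in each of 6 groups: control, AIA, AIA-cold, AIA-cold-WTD, AIA-hot and AIA-hot-WTD. Groups came from the sample titles and annotations. The labels call each array a biological replicate but give no animal numbers, so replicate numbers only name arrays and pair nothing, and whether each array came from its own animal is not stated in the sources used here. If arrays shared tissue, the p-values would measure a spread that is partly technical. Samples given other treatments are not analysed here.

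The scanner files held fluorescence intensity values per spot, read with Agilent Feature Extraction 10.7 per the submitters' processing notes. Per the file headers, the processed signal was background-subtracted and detrended on each array, with a surrogate value in place of signals too dim to measure, and was not normalized between arrays. Mean and local background intensities stood beside it, per the file headers. The authors' deposited series table held values whose scale was not stated; set against the scanner values of the same arrays they correlated with the log2 processed signal at 0.989 to 1.000. Their column medians lay between 5.40 and 5.42 and their 75th percentiles between 8.05 and 8.06, so they were taken as log2 values brought to a common distribution by the authors. Which function did so stays unknown; limma is named without a version in the submitters' processing notes. The table served only as an alternative.

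Each array had 43379 spots and 41012 gene probes. The log2 of the processed signal was taken, control spots and spots with an outlier flag (58 to 139 per array) were left out, and the array's 75th percentile over gene probes was subtracted. No spot was saturated (0 on every array). Spots of a probe were averaged on the log2 scale, which left 67 missing probe values. Probes well above background on all 3 arrays of at least 1 group were kept, 28271 in number. A gene was represented by its brightest kept probe over the 18 arrays, which gave 23606 genes or transcripts, 12055 of them with a symbol; the text says where other probes of a named gene differed by over 1.5 times. Names came from the RefSeq gene table of the rat assembly GRCr8 without its coordinates: 18028 probes matched by accession, 3168 by symbol and 400 by synonym, and 19416 kept the name in the file.

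Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of all 18 arrays with a mean per group, so that every comparison shared 1 estimate of the spread with 12 residual and 2.29 prior degrees of freedom. The 8 pairs of groups and the difference between the effects of WTD in the cold and hot models made 9 contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, with no minimum fold. Values are log2 differences with the moderated standard error, and group values are means ± SD on the log2 scale relative to the 75th percentile. A gene not well above background on any array of a group has only a bound there. Its fold is then given as "at least", from the bright group's mean against the mean over the dim group's arrays of the higher of the array's lowest signal well above background and the probe's own signal, and is left out where that ratio is under 1. The arrays' lowest such signals lay between -5.25 and -1.86 (log2), the highest on control replicate 1. The bright group's mean takes in any of its own arrays not well above background. Where it does so, the fold is not a strict bound.

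The 45 lists of pathway and cell type genes, with 528 of 650 members measured, were fixed before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives except 3. Each list was tested in each contrast with camera at a preset correlation of 0.01, adjusted over 405 tests; 48 genes with a missing value were left out. The test was repeated with a correlation estimated for each list, and fry was run beside it. Medians and members higher or lower describe a list's size, and its members were also adjusted over the list alone. That adjustment was not carried across the 405 pairs of list and contrast, so some such passes would arise with no change. An arthritis score was the mean of the 100 genes most higher less the mean of the 100 most lower in AIA than in control by limma, scaled to 0 for control and 1 for AIA, and was compared by exact two-sided permutation of arrays. Each AIA and control array was also left out in turn of choosing the genes and of setting 0 and 1, and then scored.

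Named genes followed a fixed rule. It took, in each contrast, up to 12 higher and 12 lower called genes with the largest change, a symbol that is not a placeholder and no overlap between the arrays of both groups (not required for the difference of effects), and up to 4 called members per list. In contrasts with fewer than 10 calls it added the 10 genes with a symbol and the smallest p. It also fixed 15 genes given whether or not called: Il1b, Il6, Tnf, Mmp3, Mmp9, Mmp13, Ptgs2, Ccl2, S100a8, S100a9, Acp5, Ctsk, Prg4, Ckm and Adipoq. Other names are marked as chosen after their values were seen, and some genes the rule takes are not reported here.

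The arrays lay on 5 slides, each scanned as a batch of its own. Slide 1 held the controls and AIA replicate 1, slide 2 AIA replicates 2 and 3 and AIA-hot replicates 1 and 2, and slide 3 AIA-hot replicate 3 and the AIA-hot-WTD arrays. Slide 4 held the AIA-cold arrays and AIA-cold-WTD replicate 1, and slide 5 AIA-cold-WTD replicates 2 and 3. When slide was a fixed block, 9 residual degrees of freedom remained and AIA-cold could not be compared with control, AIA or AIA-hot. As a random block the consensus correlation was 0.155. The other alternatives were normexp background correction (offset 50) of the mean signals, quantile normalization, no filter on dim probes, probes well above background on all 18 arrays, the series table, the mean of a gene's probes, the mean of the skeletal muscle list as a covariate, a fit of only the groups compared, each array left out in turn, and 50 or 250 genes in the score. Added after the array intensities were seen were array weights, a fit without control replicate 1 in contrasts that do not involve it, and score genes chosen without it.

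The code was tested on simulated data for 23558 genes, drawn from each gene's mean and spread within groups, with 50 genes changed at each fold in AIA-cold. In simulated AIA-cold against control it called 28% of the genes changed 2-fold, 72% at 4-fold, 82% at 8-fold and 90% at 16-fold, all in the right direction, with 12 unchanged genes called; the shifted list had an adjusted p of 5.91e-10 and 0 other lists were called. In simulated AIA against control with no change, 0 genes were called. The genes were drawn independently of each other. The 0 other lists therefore say nothing about false calls of lists whose genes vary together, as they may on the real arrays. Comparisons that share the controls were set beside 20 simulated sets of unchanged groups.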

Results

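RNA from the knee synovial tissue of male Lewis rats, an inbred strain that develops arthritis after adjuvant injection, was hybridised to 18 single-colour rat arrays. The labels divide the arrays into 6 groups of 3. These are normal controls, rats with adjuvant-induced arthritis (AIA), and rats with AIA in a cold or a hot model. The last 2 groups are each of these models treated with WTD, a Chinese herbal formula. How the cold and hot models were produced and how WTD was given are not stated in the sources used here, and treatment groups of the study that received other compounds are not analysed here. The titles of the 6 arrays with WTD carry the letters G, Z or D, which nothing in the labels explains, so each WTD group may hold arrays that differ in a way not resolved here. The series asks, per its design text, which constituents of WTD act against the cold form of the disease, and the comparisons below set each model against the controls, against plain AIA and against the other model, and each WTD group against its model.

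The 75th percentile of the signal lay between 201 and 331 units on 17 arrays and at 68.9 on control replicate 1. On that array 43.3% of the probes were well above background, against 56.4% to 76.6% on the others. It also stood apart in tissue make-up: the mean of its 10 measured cartilage genes was 5.55, against -2.12 and -0.44 on the other controls, on a log2 scale relative to the 75th percentile. Muscle genes were highest on AIA-hot-WTD replicate 3 (3.38), and adipocyte genes were lowest on AIA-cold-WTD replicate 1 (1.48). The correlation across probes between 2 arrays ran from 0.906 to 0.993, and from 0.951 without control replicate 1. A total of 23606 genes or transcripts were tested, of which 12055 had a gene symbol. The number of arrays limits the precision.

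**Figure D1:**
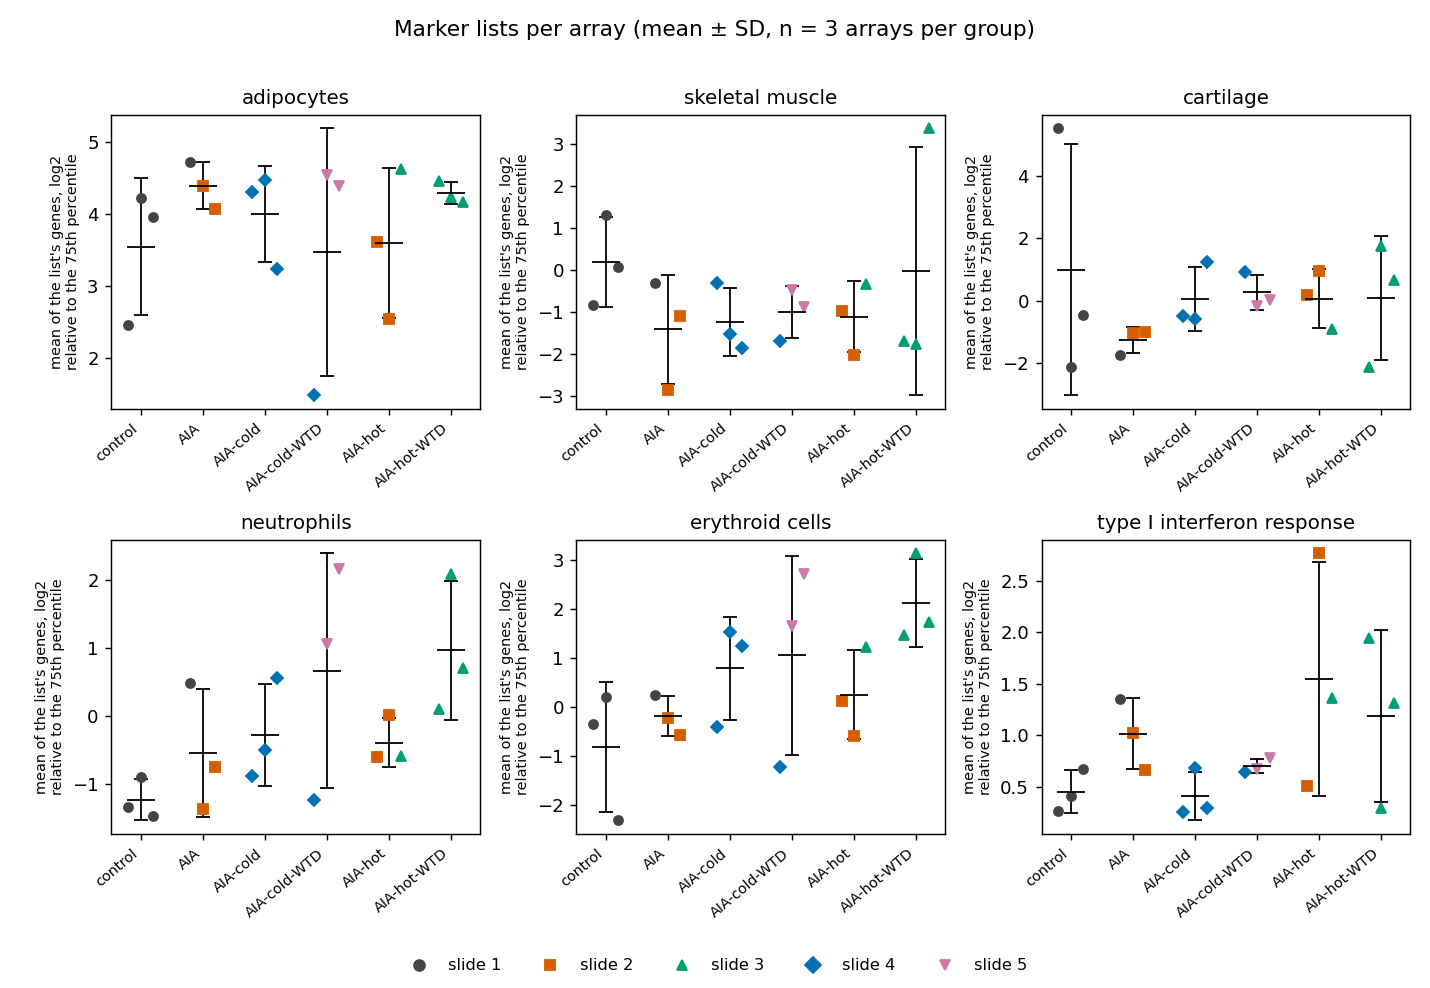
Mean log2 signal of 6 marker lists on each of the 18 arrays, relative to the array's 75th percentile, by group; points are arrays, shaped and coloured by slide, and bars give the group mean ± SD (n = 3). The cartilage genes of control replicate 1 lie at 5.55 and the muscle genes of AIA-hot-WTD replicate 3 at 3.38, apart from the other arrays of their groups.

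Plain AIA could not be told from control gene by gene, which with 3 arrays a group does not show that the difference was small. No gene passed the test, and the smallest adjusted p was 0.137, for Irak2, a kinase of interleukin-1 and Toll-like receptor signalling, and for Mat1a, which makes S-adenosylmethionine. The 10 named genes with the smallest p were all lower in AIA. Irak2 was at least 2.97-fold lower, Actrt2 at least 7.76-fold, Zbtb5 at least 8.76-fold, 1700012B07Rkl at least 4.80-fold, Wdr76 at least 2.88-fold, the olfactory receptor Or4d10 at least 2.32-fold and the clock gene Per3 at least 1.104-fold, each well above background on 0 AIA arrays. Control replicate 1 raised the control means of most of these: without it the bounds were 1.80-fold for Irak2, 3.72 for Actrt2, 4.33 for Zbtb5, 2.94 for 1700012B07Rkl, 2.20 for Wdr76, 1.23 for Or4d10 and 1.04 for Per3. Ubxn2b differed by -1.90 ± 0.33 (log2, SE), and Mat1a and Slc6a2, both well above background on 0 AIA arrays, allowed no fold. Per3 passed when adjusted over the list alone (1 lower among the clock genes, against 0 over all genes), and its other probe gave -0.35. It was not well above background on control replicate 1, so only its bound without that array is strict. Of the inflammatory genes fixed beforehand, the alarmin genes S100a9 and S100a8 differed by 2.44 ± 1.29 and 1.79 ± 1.39 (as low as 1.00 on other S100a8 probes), Il1b by 0.77 ± 0.32, the chemokine gene Ccl2 by -0.14 ± 0.63 and Il6 by -0.50 ± 0.46. The protease genes Mmp3, Mmp13 and Ctsk differed by -0.41 ± 0.66, -0.73 ± 1.85 and 0.06 ± 0.50, the osteoclast gene Acp5 by -0.21 ± 0.35, the lubricin gene Prg4 by -0.03 ± 0.28, the muscle gene Ckm by -2.26 ± 1.94 and the adipocyte gene Adipoq by 0.99 ± 0.72. Mmp9 was well above background on 0 AIA arrays and 1 control array. Tnf and Ptgs2 were well above background on 0 of the 18 arrays and were not tested in any comparison.

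With the preset correlation 10 lists were called between AIA and control, and each had an adjusted p = 0.875 with an estimated correlation. The adipocyte list had a median log2 difference of 0.87, fatty acid oxidation 0.52, the type I interferon response 0.52, oxidative phosphorylation 0.33 and the chemokines 0.23. Cartilage (-2.03), skeletal muscle (-1.55), immediate early genes (-0.58), angiogenesis (-0.36) and endothelial cells (-0.27) lay lower. None of the 10 calls held without each array in turn. No member of any list passed over all genes. The muscle call ended without control replicate 2 (-0.99) or AIA replicate 2 (-0.72). Without control replicate 1 it alone remained, and the medians of the other lists were 0.26 for adipocytes, 0.12 for fatty acid oxidation, 0.06 for oxidative phosphorylation, -0.20 for immediate early genes, 0.37 for interferon, 0.46 for chemokines, 0.05 for cartilage, 0.19 for endothelial cells and 0.04 for angiogenesis. The median for muscle with slide as a fixed block was -0.35 and for cartilage -2.17. That fit, here and in the count of calls below, rests on AIA replicate 1, the only AIA array on slide 1. limma called 0 genes and 1484 had an unadjusted p under 0.05, where 1180 would on average if no gene changed. The excess is no count of changed genes, since the number can lie well off that mean where genes vary together. Leaving out control replicate 2 gave 2 calls and leaving out control replicate 3 gave 9; the slide as a fixed block gave 13.

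AIA-cold gave the most calls against control: 126 genes passed, 57 higher and 69 lower. Zbtb16, a transcription factor that glucocorticoids induce, lay at 0.47 ± 0.29 in AIA-cold and -2.98 ± 0.24 in control (log2, SD, n = 3), a rise of 3.46 ± 0.45 (SE; adjusted p = 0.0136), although its other probe gave 0.87. Fkbp5, a chaperone that binds the glucocorticoid receptor, rose by 2.50 ± 0.35 (adjusted p = 0.0147; 1.59 to 2.62 over its 3 probes). Over all genes 2 members of the glucocorticoid list rose and none fell, though the list itself was not called with the preset correlation. Adjusted over the list alone 4 rose (Fkbp5, Zbtb16, Klf9 and Pdk4) and 1 fell (Dusp1). Gulo, which completes vitamin C synthesis, rose by 3.13 ± 0.57 and the lysophospholipase gene Pnpla7 by 2.04 ± 0.33. Alox15b, a lipoxygenase of arachidonic acid, was at least 1.95-fold higher and the transglutaminase gene Tgm1 at least 2.51-fold, both well above background on 0 control arrays, with bounds of 3.06-fold and 3.94-fold without control replicate 1. Gprin3 rose by 3.83 ± 0.78, the lectin gene Cd209f by 3.05 ± 0.59, the imprinted zinc-finger gene Zim1 by 2.46 ± 0.33, and the chemokine genes Ccl6 and Ccl3 by 1.94 ± 0.40 and 1.93 ± 0.24.

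Among the genes lower in AIA-cold, the glucose transporter gene Slc2a1 fell by 1.31 ± 0.21 (adjusted p = 0.0235) and was the only member of the hypoxia list to pass, and Sqle, squalene epoxidase of cholesterol synthesis, fell by 2.05 ± 0.39 (adjusted p = 0.0376). Irak2 fell by 2.81 ± 0.54, Ubxn2b by 2.04 ± 0.33, 1700012B07Rkl by 2.82 ± 0.49, Slurp1 by 1.81 ± 0.31, the hedgehog-binding gene Hhip by 1.73 ± 0.35 and the protocadherin gene Pcdh10 by 1.42 ± 0.28. Wdr76 was at least 5.33-fold lower, Zfp385b at least 3.26-fold and Megf11 at least 3.01-fold, each well above background on 0 AIA-cold arrays. Zfp385b and Megf11 were not well above background on control replicate 1, and their bounds without it were 2.56-fold and 2.75-fold. The acetylcholine receptor gene Chrna9, lower as well, was well above background on 0 AIA-cold arrays and 1 control array. Its fold was given as 2.34, and as 1.48 without control replicate 1. Neither is a strict bound, as the control mean holds arrays not well above background. All of these named genes had adjusted p from 0.0136 to 0.0467. In none of them did the 3 arrays of AIA-cold overlap with those of control. The naming rule required this of all but the list members, so it adds no support. Without control replicate 1, Irak2, Ccl6, Cd209f, Gprin3, Gulo, Pnpla7, Slc2a1, Slurp1, Hhip, Pcdh10, Zfp385b, Megf11 and Chrna9 did not pass (adjusted p from 0.0505 to 0.107); there Irak2 was at -2.09 and Ccl6 at 1.31. Of the genes fixed beforehand, S100a9 and S100a8 differed by 3.09 ± 1.29 and 2.55 ± 1.39, Il1b by 1.17 ± 0.32 (adjusted p = 0.0896), Ccl2 by -0.01 ± 0.63, Mmp3 by -0.18 ± 0.66, Mmp13 by -0.16 ± 1.85 and Mmp9 by -0.61 ± 1.94. Ctsk differed by 0.70 ± 0.50, Acp5 by -0.26 ± 0.35, Prg4 by -0.75 ± 0.28, Ckm by -2.44 ± 1.94 and Adipoq by 0.73 ± 0.72. Il6 was well above background on 0 AIA-cold arrays and 1 control array, and had an adjusted p of 0.0931. It came out 2.54-fold lower, and 1.64-fold without control replicate 1. Neither is a strict bound, as the control mean holds arrays not well above background. None of these 13 passed.

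In AIA-cold the glycolysis and cholesterol synthesis lists lay lower and the T and NK cell and MHC class II lists higher than in control with the preset correlation, each with an adjusted p = 0.875 with an estimated correlation. Glycolysis had a median of -0.57 with 13 of 15 members lower; 0 passed over all genes and 7 fell when adjusted over the list alone, among them Ldha (-1.01), Pkm (-0.90) and Gapdh (-0.79). Cholesterol synthesis had a median of -0.71 with 11 of 13 members lower, 1 of them (Sqle) over all genes and 4 adjusted over the list alone, including Idi1 (-0.89) and Mvd (-0.88). Immediate early genes had a median of -0.63, with 0 and 6 lower, among them Nr4a1 (-1.85) and Egr1 (-1.05), and angiogenesis -0.45. T and NK cells had a median of 0.70, with 0 members over all genes and 5 adjusted over the list alone, among them Nkg7 (1.97) and Prf1 (1.40). MHC class II had a median of 0.59, with 0 and 5, among them RT1-Da (1.54) and Cd74 (1.30). Complement (0.37), erythroid cells (1.46) and fatty acid oxidation (0.35, with Cpt1a passing over the list alone) also lay higher. Of the chemokines 1 passed over all genes (Ccl3) and 4 adjusted over the list alone, though the list itself was not called. These members were chosen after their values were seen. The other 5 called lists also had an adjusted p = 0.875 with an estimated correlation. Without control replicate 1 the median was 0.33 for MHC class II and -0.39 for immediate early genes, neither called, and -0.02 for complement, 0.00 for fatty acid oxidation and -0.06 for angiogenesis, while glycolysis (-0.49), cholesterol synthesis (-0.70) and T and NK cells (0.88) stayed called with the preset correlation. The calls of glycolysis and cholesterol synthesis held without each array in turn, while T and NK cells (0.53) and erythroid cells (0.60) were not called without control replicate 3.

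limma gave 4405 genes with an unadjusted p under 0.05 in AIA-cold against control. With slide as a random block 0 genes passed and with only these 6 arrays in the fit 0 passed; as no slide held both groups, slide and group could not be separated here. The count was 1 without AIA-cold replicate 1, 0 without AIA-cold replicate 2, 79 without AIA-cold replicate 3, 45 without control replicate 1 (29 of them among the 126) and 297 without control replicate 2. Quantile normalization gave 130 higher and 92 lower, and the values of the series table gave 133 and 94. Relative to an all-gene median within 0.06 of 0 under the scalings used, normexp background correction shifted that median to -0.21 for AIA-cold, -0.19 for AIA-hot and -0.14 for AIA against control.

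**Figure D2:**
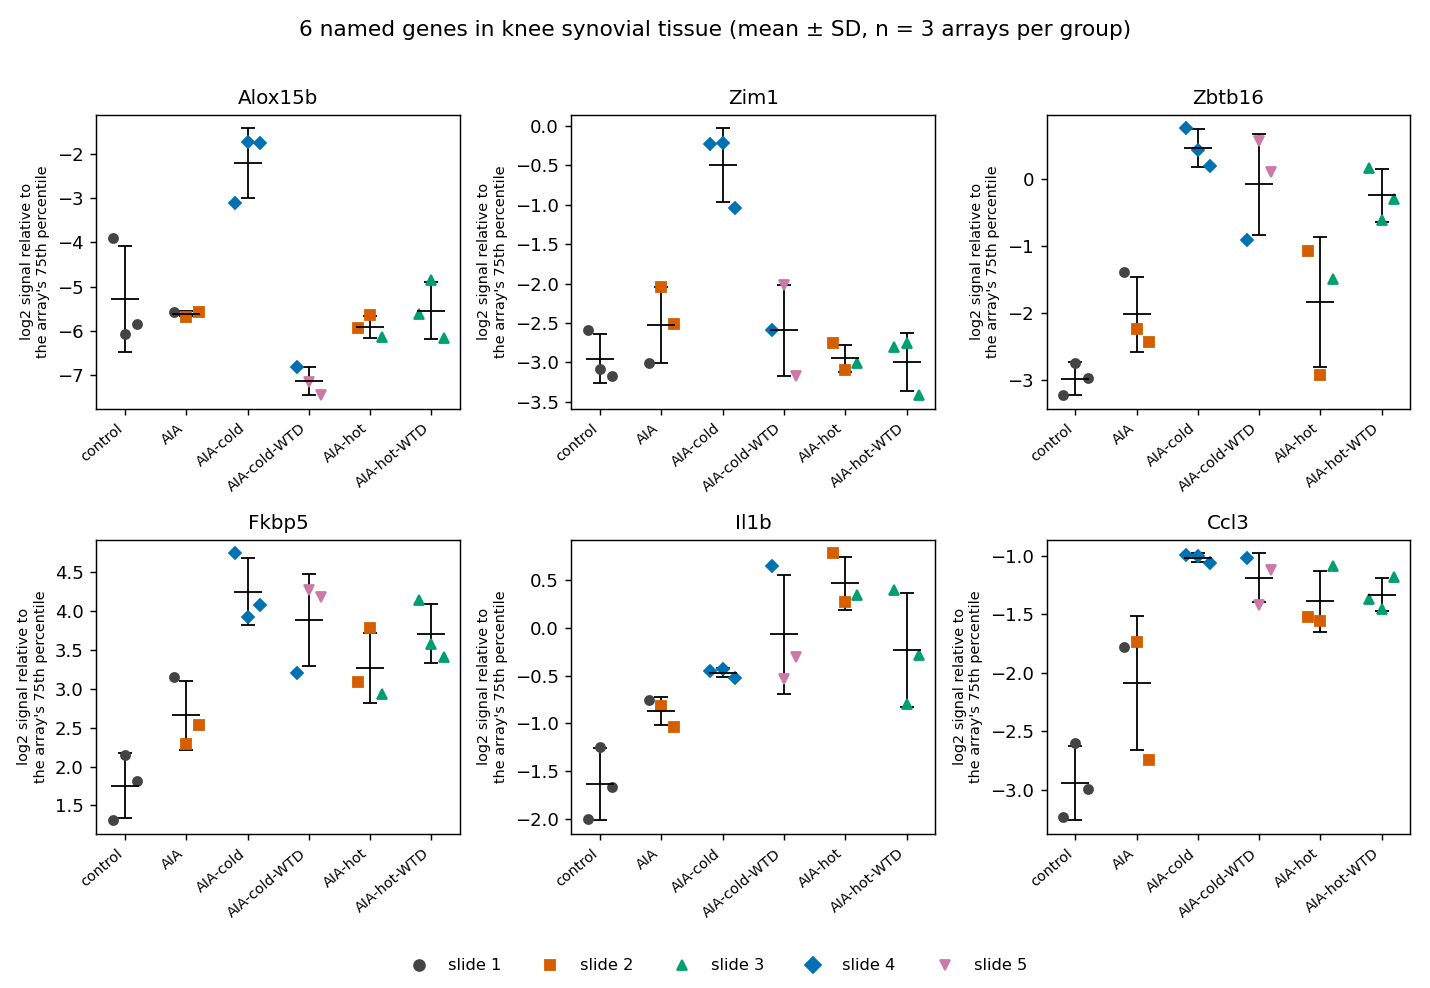
Log2 signal of 6 named genes relative to the array's 75th percentile on each of the 18 arrays, by group; points are arrays, shaped and coloured by slide, and bars give the group mean ± SD (n = 3). Alox15b lies at -2.19 ± 0.79 in AIA-cold and at -7.15 ± 0.32 in AIA-cold-WTD, where 0 arrays were well above background.

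AIA-hot against control gave fewer calls: 13 genes passed, 3 higher and 10 lower. Il1b, which encodes the cytokine interleukin-1 beta, lay at 0.47 ± 0.28 in AIA-hot and -1.64 ± 0.38 in control (SD, n = 3), a rise of 2.11 ± 0.32 (SE; adjusted p = 0.0343), and Ccl3 rose by 1.56 ± 0.24 (adjusted p = 0.0343). Irak2 was at least 3.66-fold lower (adjusted p = 0.0216) and Actrt2 at least 9.57-fold lower, each well above background on 0 AIA-hot arrays, with bounds of 2.23-fold and 4.59-fold without control replicate 1. Ubxn2b fell by 2.11 ± 0.33, Ms4a8 by 1.89 ± 0.29, Pkhd1l1 by 1.66 ± 0.26, Plxdc1 by 1.34 ± 0.21, Plac9 by 1.22 ± 0.20 and the phosphatase gene Dusp14 by 0.90 ± 0.13, with adjusted p from 0.0343 to 0.047. The arrays of the groups did not overlap for any of these, which the naming rule required except of list members and genes fixed beforehand. Without control replicate 1, Il1b, Ccl3, Actrt2, Ms4a8, Pkhd1l1, Plxdc1 and Plac9 did not pass (adjusted p from 0.0824 to 0.102). The other probe of Plxdc1 gave -0.58. Of the other genes fixed beforehand, none passed: S100a9 differed by 3.05 ± 1.29, S100a8 by 2.31 ± 1.39 (as low as 1.30 on its other probes), Ccl2 by 1.24 ± 0.63, Il6 by -0.37 ± 0.46, Mmp13 by 2.24 ± 1.85 and Mmp3 by 0.27 ± 0.66. Ctsk differed by 0.87 ± 0.50, Acp5 by -0.46 ± 0.35, Prg4 by -0.41 ± 0.28, Ckm by -2.12 ± 1.94 and Adipoq by 0.22 ± 0.72. Mmp9 was well above background on 0 AIA-hot arrays.

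Several immune lists lay higher in AIA-hot than in control with the preset correlation. With an estimated correlation, T and NK cells and chemokines had an adjusted p = 0.675 and the other 11 called lists an adjusted p = 0.875. All 15 measured genes of the type I interferon response were higher, with a median of 1.15 that was 0.46 without AIA-hot replicate 2, although 0 passed over all genes or over the list alone; the interferon mean per array was 2.77 on AIA-hot replicate 2, 1.36 on replicate 3 and 0.51 on replicate 1. T and NK cells had a median of 0.94 with 12 of 13 higher, of which 0 passed over all genes and 4 adjusted over the list alone, among them Nkg7 (1.82), Cd8b (1.81) and Prf1 (1.71). Chemokines had a median of 0.86, with 1 member over all genes (Ccl3) and 5 adjusted over the list alone, including Ccl4 (1.59) and Ccl5 (2.14). Complement had a median of 0.45, with 0 and 3 (C2, C3 and Cfb; C3 3.06). Of the inflammatory cytokines 1 passed over all genes (Il1b) and 2 adjusted over the list alone, with Il1rn. Members other than Il1b and Ccl3 were chosen after their values were seen. MHC class II (0.78), matrix proteases (0.33), fibrillar collagens (0.39), erythroid cells (0.69) and B and plasma cells (0.69) also lay higher, and endothelial cells (-0.44), angiogenesis (-0.48), glycolysis (-0.40) and cholesterol synthesis (-0.43, with Sqle passing over the list alone) lower. The calls of the chemokines, the interferon response, T and NK cells and glycolysis held without each array in turn, with the chemokines at 1.41 without AIA-hot replicate 3. Among the calls that ended, complement was at 0.11 and MHC class II at 0.61 without control replicate 1, fibrillar collagens at 0.10, matrix proteases at 0.20 and cholesterol synthesis at -0.32 without AIA-hot replicate 2, erythroid cells at 0.14 without control replicate 3 and B and plasma cells at 0.50 without AIA-hot replicate 1. Without control replicate 1 the interferon, T and NK cell and chemokine medians were 1.00, 1.29 and 1.04, and those of endothelial cells and angiogenesis -0.01 and -0.07. With slide as a fixed block glycolysis turned and was called higher with the preset correlation, at a median of 0.20, and cholesterol synthesis had -0.04. That fit, here and in the count of calls below, reaches the controls only through AIA replicate 1, the single AIA array on slide 1.

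limma gave 2857 genes with an unadjusted p under 0.05 in AIA-hot against control, and 22 calls after quantile normalization (8 higher and 14 lower). With slide as a random block 0 passed, with normexp 0, with the muscle score as a covariate 0, and with slide as a fixed block 5, none of them among the 13; there Il1b differed by 2.34 (adjusted p = 0.272) and Ccl3 by 1.87 (adjusted p = 0.293). The count was 2 without AIA-hot replicate 1, 0 without replicate 2, 61 without replicate 3, 7 without control replicate 1 (5 of them among the 13) and 49 without control replicate 2.

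AIA-cold and AIA-hot shared 5 calls against control, Ccl3 higher and Irak2, Ubxn2b, Dusp14 and the transcript BQ204855 lower, where independent lists would share 0.0072 and 0.029. Genes called in the same direction in all 3 comparisons with control numbered 0, by limma. With 0 calls in AIA against control the count could not be higher, so the 0 in simulated unchanged groups says nothing about sharing. Across genes, which are not independent replicates, the log2 differences of AIA-cold and AIA-hot from control correlated at r = 0.743, those of AIA and AIA-hot at 0.62 and those of AIA and AIA-cold at 0.619. Simulated unchanged groups set against the same controls gave 0.5, 0.499 and 0.497. The covariances were 0.211, 0.13 and 0.149, each against 0.061 simulated. The simulation gave all arrays the same spread for a gene, while control replicate 1 stood apart in signal and tissue make-up. The simulated values may therefore be too low, and the excess over them is not read as a shared response. The 3 control arrays were too few to divide, so part or all of the overlap may come from the shared controls.

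AIA-cold against plain AIA asked what the cold model adds to the arthritis. The fatty acid and triglyceride synthesis list lay lower with the preset correlation, with a median of -1.09 and 11 of 12 members lower, and had an adjusted p = 0.875 with an estimated correlation, as had the other 10 called lists. Of these 0 passed over all genes and 4 adjusted over the list alone, Fasn (-4.33), Scd (-4.28), Acaca (-2.48) and Me1 (-1.93), named after their values were seen. Fasn, fatty acid synthase, lay at 3.32 ± 0.23 in AIA-cold and 7.66 ± 1.73 in AIA (SD, n = 3). Cholesterol synthesis (-0.55, with Fdft1 and Dhcr7 passing over the list alone), oxidative phosphorylation (-0.53), glycolysis (-0.34, with Ldha passing over the list alone) and the interferon response (-0.43) were lower too. T and NK cells (0.43), macrophages (0.31), cell cycle (0.51), fibrillar collagens (0.42), MHC class II (0.60) and erythroid cells (1.21) were higher. The calls of fatty acid and cholesterol synthesis held without each array in turn, the latter at -0.36 without AIA replicate 1, and the other 9 did not. Without AIA-cold replicate 3 the medians were 0.15 for macrophages, 0.22 for cell cycle, 0.26 for fibrillar collagens, 0.34 for MHC class II, 0.72 for erythroid cells and -0.45 for the interferon response, none called. Oxidative phosphorylation (-0.28) and glycolysis (-0.23) were not called without AIA replicate 1, nor T and NK cells (0.42) without AIA replicate 3. The glucocorticoid list was not called. On it 0 genes passed over all genes and 2, Fkbp5 (1.59) and Zbtb16 (2.49, with 0.63 on its other probe), adjusted over the list alone.

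Gene by gene, limma called 0 in AIA-cold against AIA, with 2136 genes at an unadjusted p under 0.05. The 10 named genes with the smallest p were Alox15b (at least 2.41-fold higher; adjusted p = 0.066), Tgm1 (at least 3.10-fold higher), Or10c1 (at least 1.76-fold higher), Zim1 (2.03 ± 0.33), Zbtb16, Paqr5 (1.81 ± 0.33), Olr1621 (-1.50 ± 0.24), Zfp185 (-2.05 ± 0.37), Rspo2 (-1.17 ± 0.22) and Myo1c (-0.72 ± 0.14), with adjusted p up to 0.171. In a fit without the dim control array, chosen after the array intensities were seen, 76 genes passed, 20 higher and 56 lower, with all 10 of these among them. No slide held both groups, and leaving out a single array of either group gave 0 to 4 calls, 4 without AIA replicate 1 or 2.

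AIA-hot against plain AIA asked the same of the hot model. With the preset correlation 16 lists were called, and with an estimated correlation T and NK cells had an adjusted p = 0.675 and the other 15 an adjusted p = 0.875. T and NK cells had a median of 0.78 with 11 of 13 higher, 0 over all genes and 4 adjusted over the list alone, among them Cd3g (2.10) and Zap70 (1.73). Fibrillar collagens had a median of 0.74 with 15 of 17 higher, the cell cycle list 0.68 with 14 of 15 higher and the interferon response 0.57 with 15 of 15 higher. Chemokines (0.56), MHC class II (0.63), complement (0.32), immediate early genes (0.39), NF-kB targets (0.25), matrix proteases (0.22) and cartilage (1.01) were higher as well. Fatty acid and triglyceride synthesis (-1.23, 12 of 12 lower), adipocytes (-0.85, 14 of 14 lower), fatty acid oxidation (-0.58), oxidative phosphorylation (-0.53) and cholesterol synthesis (-0.37) were lower. The calls of 6 lists held without each array in turn: T and NK cells, chemokines, complement, fibrillar collagens, fatty acid oxidation, and fatty acid and triglyceride synthesis. Their sizes moved, except for T and NK cells: complement was at 0.15, chemokines at 0.36 and fatty acid oxidation at -0.37 without AIA-hot replicate 2, collagens at 0.35 without AIA-hot replicate 1 and 1.22 without AIA-hot replicate 3, and fatty acid and triglyceride synthesis at -0.71 without AIA replicate 1. Without AIA-hot replicate 2 the medians were -0.03 for interferon, -0.31 for adipocytes, 0.28 for MHC class II, 0.08 for NF-kB targets, 0.14 for immediate early genes and 0.81 for cartilage, none called. Without AIA-hot replicate 1 cell cycle (0.25) and matrix proteases (0.17) were not called, nor cholesterol synthesis (-0.08) and oxidative phosphorylation (-0.26) without AIA replicate 1.

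limma called 0 genes in AIA-hot against AIA, and 1210 had an unadjusted p under 0.05. With slide as a fixed block, which rests on the 4 arrays of these groups that shared a slide, 142 passed, 122 higher and 20 lower. Of the 10 named genes with the smallest p, the neuronal tubulin gene Tubb3 was at 1.78 and Pkhd1l1 at -1.49 in that fit (adjusted p = 0.039 and 0.0377), against 1.83 ± 0.42 and -1.18 ± 0.26 without the block (adjusted p = 0.839 and 0.758). The others were the centromere gene Cenpm (at least 1.24-fold higher), Hrob (at least 1.20-fold), Mfsd10 (at least 1.43-fold), Spred3 (at least 1.55-fold), Kcnab2 (at least 1.098-fold), Mat1a, Map4k1 (0.96 ± 0.21) and Thap6 (-0.49 ± 0.11). Il1b passed when adjusted over the list alone and not over all genes. Leaving out AIA-hot replicate 3 gave 3 calls.

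AIA-cold and AIA-hot differed by 2 genes, both higher in AIA-cold. Alox15b lay at -2.19 ± 0.79 in AIA-cold and -5.92 ± 0.25 in AIA-hot, where 0 arrays were well above background, at least 2.98-fold higher (adjusted p = 0.0382). Zim1 lay at -0.49 ± 0.47 and -2.95 ± 0.17, a difference of 2.46 ± 0.33 (adjusted p = 0.0382). Zbtb16 was at 2.30 ± 0.45 (adjusted p = 0.309; 1.08 on its other probe) and passed when adjusted over the glucocorticoid list alone. The growth factor gene Fgf7 was at -0.89 ± 0.14, Chl1 at -1.39 ± 0.24, Ptk7 at -1.24 ± 0.23, Cenpm at -1.44 ± 0.28, Zfp185 at -2.19 ± 0.37, Smad7 at 0.79 ± 0.14 and Or10c1 at least 2.17-fold higher. None of these passed. Fgf7 passed in a limma fit without the dim control array, chosen after the array intensities were seen (adjusted p = 0.0237). The 4 measured keratinocyte genes, close to background, had a median difference of 0.14. The interferon response was lower in AIA-cold, with 15 of 15 genes and a median of -0.92, and had an adjusted p = 0.875 with an estimated correlation, as had the other 9 called lists. Mx1, which blocks viral replication, differed by -1.92 and Isg15, a ubiquitin-like protein, by -1.96, both named after their values were seen. These sizes rested largely on AIA-hot replicate 2: on AIA-hot replicates 1 to 3 Mx1 lay at -3.24, 0.25 and -2.15 and Isg15 at 2.03, 5.70 and 3.68. Without that array the list's median was -0.44, still called with the preset correlation. NF-kB targets (-0.35), chemokines (-0.40), immediate early genes (-0.40), T and NK cells (-0.40, with Cd8a passing over the list alone), cholesterol synthesis (-0.27), glycolysis (-0.19) and apoptosis regulators (-0.14) were lower and fatty acid oxidation (0.42) and the glucocorticoid response (0.20) higher. Only the interferon call held without each array in turn. Without AIA-cold replicate 3 T and NK cells (-0.08), chemokines (-0.25) and glycolysis (-0.14) were not called. Apoptosis regulators (-0.05), cholesterol synthesis (-0.18) and the glucocorticoid response (0.14) were not called without AIA-hot replicate 1, nor NF-kB targets (-0.24), immediate early genes (-0.25) and fatty acid oxidation (0.24) without AIA-hot replicate 2. limma gave 1296 genes with an unadjusted p under 0.05; no slide held both groups, 0 genes passed with slide as a random block, and 0 passed without AIA-cold replicate 2, AIA-hot replicate 1 or AIA-hot replicate 2.

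WTD in the cold model was followed by lower Alox15b. It lay at -7.15 ± 0.32 in AIA-cold-WTD and -2.19 ± 0.79 in AIA-cold (SD, n = 3), with 0 treated arrays well above background, at least 7.01-fold lower (adjusted p = 0.00241). The unnamed transcript BF549735 fell by 2.01 (adjusted p = 0.013), and these were the 2 calls. Alox15b passed without each of the 6 arrays in turn and with slide as a random block (adjusted p = 0.00807). Its adjusted p was 0.0528 when slide was a fixed block, 0.395 with only these 6 arrays in the fit and 0.737 after normexp, which adds an offset that compresses dim signals. The next genes did not pass: Zim1 was at -2.10 ± 0.33, Zfp185 at 2.41 ± 0.37, Ccdc103 at least 1.59-fold higher and Zfat at -0.99 ± 0.15, each with an adjusted p = 0.0541, and other probes of Zfat reached 0.12. Dcxr (0.72 ± 0.13), Dmpk (0.67 ± 0.14), Ltbp1 (-0.63 ± 0.13), Tdh (-1.21 ± 0.25) and the actin-binding thymosin gene Tmsb10 (-1.24 ± 0.26) followed. In a limma fit without the dim control array, chosen after the array intensities were seen, Zfat, Zfp185, Ccdc103 and Zim1 passed (adjusted p from 0.0126 to 0.049).

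Of the inflammatory genes fixed beforehand none passed between AIA-cold-WTD and AIA-cold. Il1b differed by 0.40 ± 0.32 (0.20 on its other probe), S100a8 by 1.86 ± 1.39, S100a9 by 1.57 ± 1.29, Ccl2 by 0.55 ± 0.63 and Mmp9 by 2.73 ± 1.94, and Il6 was at least 1.22-fold higher. Mmp3 differed by -0.26 ± 0.66, Mmp13 by 1.69 ± 1.85, Ctsk by 0.07 ± 0.50, Acp5 by 0.27 ± 0.35, Prg4 by 0.16 ± 0.28, Ckm by 0.46 ± 1.94 and Adipoq by -0.85 ± 0.72. All 15 cell cycle genes lay higher with WTD, with a median of 0.70, called with the preset correlation and at an adjusted p = 0.875 with an estimated one. Among them was the proliferation marker Mki67 (1.11), named after its value was seen. Without single arrays the list's median ran from 0.51 to 0.88 and stayed called. The osteoblast and bone list had a median of 1.51 (7 of 9 higher; adjusted p = 0.262) and neutrophils 0.88 (7 of 9 higher; adjusted p = 0.0959), neither called. Bglap, the osteocalcin gene, lay at 1.89, 5.29 and 4.62 on the treated arrays and -2.62, -1.999 and 5.70 on the AIA-cold arrays, and the neutrophil and erythroid means of AIA-cold-WTD replicate 3 were 2.17 and 2.72. Glycolysis (0.32) and cholesterol synthesis (0.29) lay higher and adipocytes (-0.66) and the glucocorticoid response (-0.13) lower. Adipocytes had an adjusted p = 0.881 with an estimated correlation and these other 3 lists an adjusted p = 0.875. Without AIA-cold-WTD replicate 3 the medians were 0.10 for glycolysis and 0.15 for cholesterol synthesis, and without AIA-cold-WTD replicate 1 that of the glucocorticoid response was -0.10, none called. The adipocyte median was 0.26 without AIA-cold-WTD replicate 1, the array with the lowest adipocyte signal. With slide as a fixed block, which rests on that array against the AIA-cold arrays, the medians were -2.60 for adipocytes, -0.07 for glycolysis, -0.21 for cholesterol synthesis and 0.83 for cell cycle. Members called over all genes numbered 0, and adjusted over the list alone Notch3 and Hbb-b1 were lower. limma gave 1437 genes with an unadjusted p under 0.05. It called 82 without AIA-cold-WTD replicate 1, 4 without AIA-cold replicate 3, 1 without AIA-cold replicate 2 or AIA-cold-WTD replicate 2 or 3, and 32 with slide as a fixed block.

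WTD in the hot model gave no call. limma called 0 genes, with a smallest adjusted p of 0.999, and 539 had an unadjusted p under 0.05, fewer than the 1180 expected on average if no gene changed. Il1b differed by -0.70 ± 0.32, Ccl2 by -0.96 ± 0.63, S100a8 by 2.58 ± 1.39, S100a9 by 2.18 ± 1.29, Mmp3 by -0.30 ± 0.66 and Mmp13 by -1.06 ± 1.85; Il6 was at least 1.82-fold lower and Mmp9 at least 2.68-fold higher. Ctsk differed by -0.40 ± 0.50, Acp5 by 0.50 ± 0.35, Prg4 by 0.08 ± 0.28, Ckm by 1.71 ± 1.94 and Adipoq by 0.61 ± 0.72. The 10 named genes with the smallest p, all at an adjusted p = 0.999, included the mesothelin gene Msln (-2.52 ± 0.72), Crispld2 (-1.32 ± 0.37), Sel1l3 (-2.52 ± 0.76), Zbtb16 (1.59 ± 0.45; 0.66 on its other probe), Zfp568 (1.62 ± 0.46), Ccdc18 (1.097 ± 0.298) and Sgsm1 (0.66 ± 0.18). The water channel gene Aqp3 was at least 2.31-fold higher, and Olr1093 and Gria2 allowed no fold. Zbtb16 passed when adjusted over the glucocorticoid list alone, which takes no account of the other lists and contrasts.

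With the preset correlation 13 lists were called for WTD in the hot model, each with an adjusted p = 0.875 with an estimated correlation. Those that lay higher were erythroid cells (1.84, 9 of 9 genes), skeletal muscle (1.24), neutrophils (0.98), adipocytes (0.67), fatty acid and triglyceride synthesis (0.61), brown fat (0.53), fatty acid oxidation (0.36), oxidative phosphorylation (0.33), prostaglandin and leukotriene synthesis (0.27) and cell cycle (0.21). Fibrillar collagens (-0.46, 16 of 17 genes), T and NK cells (-0.45) and the interferon response (-0.41) lay lower. Only the erythroid call held without each array in turn. With slide as a fixed block, which rests on AIA-hot replicate 3 against the 3 treated arrays, fibrillar collagens turned and were called higher, at a median of 0.42. Medians there were also -0.35 for adipocytes, -0.20 for fatty acid and triglyceride synthesis, -0.19 for fatty acid oxidation, -0.14 for oxidative phosphorylation and 1.32 for cell cycle. The muscle median was -0.56 and that of prostaglandin and leukotriene synthesis 0.06 without AIA-hot-WTD replicate 3, neither called. Without AIA-hot replicate 2 the interferon median was 0.16, and adipocytes (0.16), fatty acid and triglyceride synthesis (0.25), fatty acid oxidation (0.13), oxidative phosphorylation (0.17), brown fat (0.29) and fibrillar collagens (-0.28) were no longer called. Collagens (-0.25) were not called without AIA-hot replicate 1 either, nor T and NK cells (-0.29), neutrophils (0.79) and cell cycle (-0.14) without AIA-hot-WTD replicate 2. Neutrophils were at 0.47, still called, without AIA-hot replicate 2 and at 1.64, not called, without AIA-hot replicate 3.

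**Figure D3:**
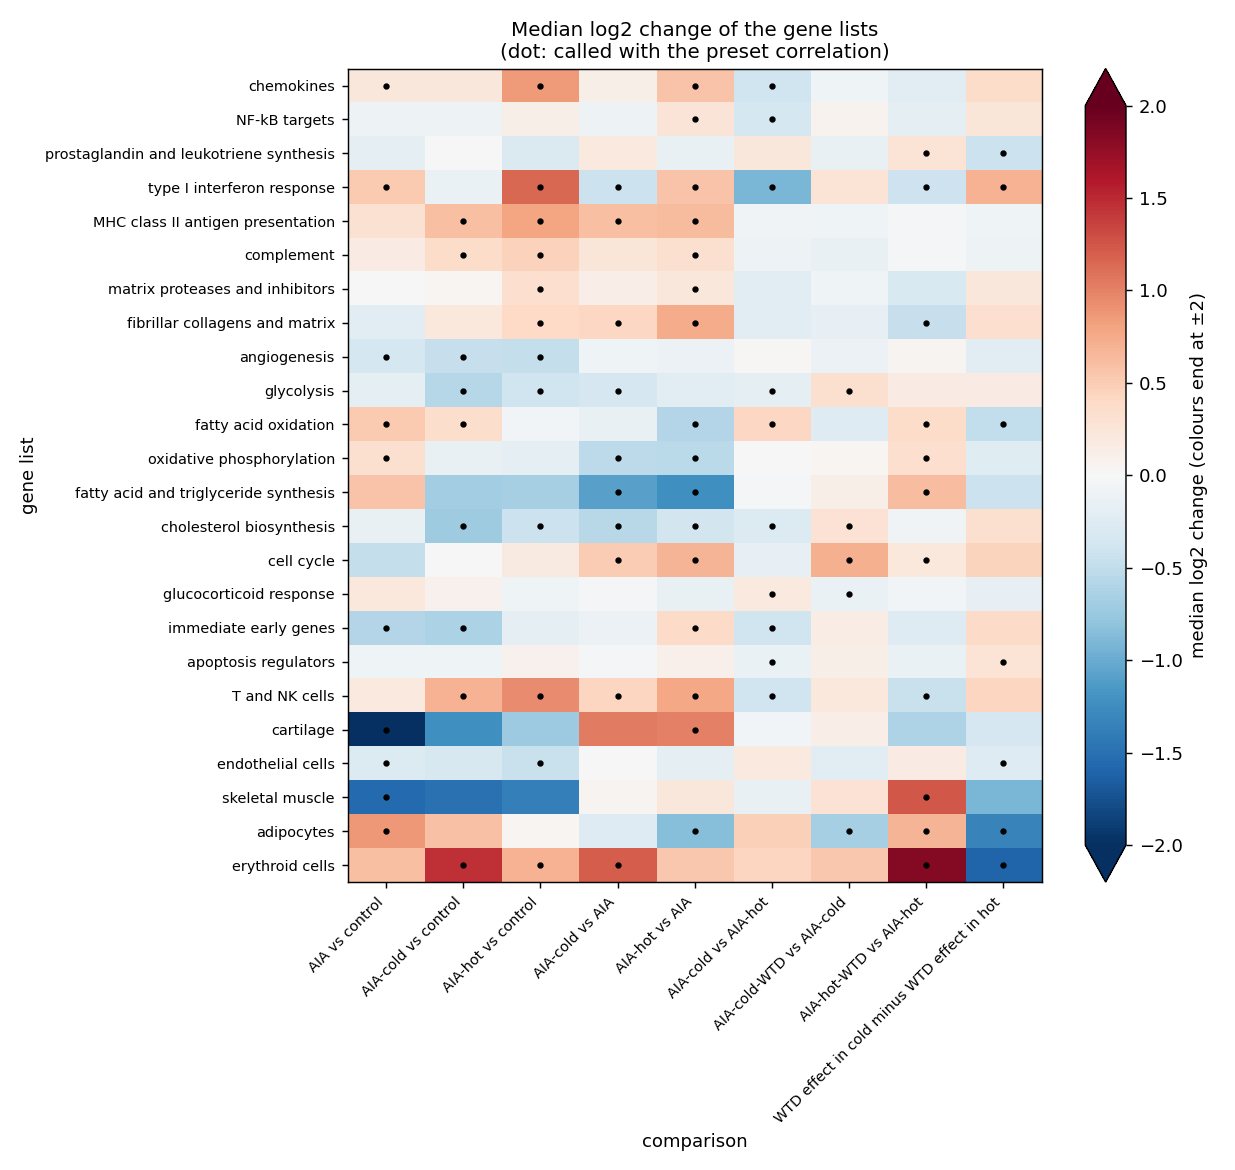
Median log2 difference of 24 gene lists, those called in 2 or more comparisons, in each of the 9 comparisons; colour gives the median, ending at ±2, and a dot marks a call with the preset correlation. The interferon row reads 1.15 for AIA-hot against control and -0.92 for AIA-cold against AIA-hot; 0 of the dots remained with an estimated correlation.

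Whether WTD acted differently in the cold and hot models was tested directly. limma called 0 genes, and 990 had an unadjusted p under 0.05. Alox15b came nearest (adjusted p = 0.0662); it was well above background on 0 arrays of AIA-cold-WTD, AIA-hot and AIA-hot-WTD, so no size is given. A fit without the dim control array, chosen after seeing the intensities, gave an adjusted p = 0.00213. Zfp185 was at 3.00 ± 0.53 (log2, SE), Ptk7 at 1.67 ± 0.32, Tmem52 at -0.94 ± 0.20, Olfml2a at 0.97 ± 0.22 (as low as 0.33 over its 4 probes), Zim1 at -2.06 ± 0.46, Zfat at -0.92 ± 0.22 (as small as -0.39 over its 3 probes), Rspo2 at 1.31 ± 0.31, Gsdma at -2.12 ± 0.52 and Cenpm at 1.65 ± 0.40, with adjusted p from 0.4 to 0.988. Of the genes fixed beforehand, Il1b was at 1.099 ± 0.447, Ccl2 at 1.51 ± 0.89, Mmp13 at 2.76 ± 2.62, Mmp3 at 0.04 ± 0.94, S100a8 at -0.71 ± 1.97 (-1.08 on another probe) and S100a9 at -0.61 ± 1.83. Ctsk was at 0.48 ± 0.71, Acp5 at -0.23 ± 0.49, Prg4 at 0.08 ± 0.39, Ckm at -1.25 ± 2.74 and Adipoq at -1.46 ± 1.02. Il6 was well above background on 0 arrays of AIA-cold and of AIA-hot-WTD, and Mmp9 on 0 of AIA-hot, so no size is given for them. None of these passed. The adjusted p of Alox15b was 0.418 with slide as a fixed block, and 9 genes passed without AIA-cold-WTD replicate 1 and 2 without AIA-cold replicate 1.

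A score of the 100 genes most higher and the 100 most lower in AIA than in control was chosen on those 6 arrays and set to 0 for control and 1 for AIA. It did not separate AIA from control on arrays that took no part in the choice. Left out in turn, the controls scored 0.605, 0.668 and 0.58 and the AIA arrays 0.456, 0.624 and 0.475, a check added after the scores were seen. Distances of the other groups from 0 and 1 are therefore not read as likeness to AIA or control. The score was 0.81 ± 0.13 in AIA-cold, 0.63 ± 0.21 in AIA-cold-WTD, 0.78 ± 0.23 in AIA-hot and 0.84 ± 0.15 in AIA-hot-WTD (SD, n = 3). The difference with WTD was -0.177 in the cold model (exact two-sided permutation p = 0.3) and 0.064 in the hot model (exact p = 0.6), and AIA-cold and AIA-hot differed by 0.028 (exact p = 0.9). With 3 arrays against 3, an exact p cannot be under 0.1. The difference in the cold model was -0.055 without AIA-cold-WTD replicate 1, which alone lay at 0.385.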

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

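All tests of explanations below, and the counts of splits, were written after the results they bear on had been seen; the differences between the effects of WTD in the cold and hot models were planned. For 3 of the slide tests an earlier form was replaced once its outcome was known, and the skin test was read anew, as stated with each.

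The effect of WTD differed between the models in 7 gene lists by the direct test of the difference with the preset correlation, and in none with an estimated correlation (adjusted p = 0.875 for each). Prostaglandin and leukotriene synthesis had a median log2 difference of -0.426 (12 of 14 genes lower in the cold model; adjusted p = 0.00676), not passing without AIA-cold-WTD replicate 1 (-0.4) or AIA-hot-WTD replicate 3 (-0.256). The type I interferon response had 0.699 (14 of 15 genes higher; adjusted p = 0.0116), 0.123 without AIA-hot replicate 2, 0.258 without AIA-hot-WTD replicate 2 and 0.384 with slide as a fixed block (adjusted p = 0.631); it also did not pass without AIA-cold replicate 3 (0.704) or AIA-cold-WTD replicate 3 (0.731). Fatty acid oxidation had -0.492 (14 of 15 lower; adjusted p = 0.0049), and -0.22 without AIA-cold-WTD replicate 1 or -0.385 without AIA-hot replicate 2, neither passing. Apoptosis regulators had 0.275 (12 of 15 higher; adjusted p = 0.0425), with 0.132 under slide as a fixed block (adjusted p = 0.422), and leaving out any of 8 of the 12 arrays, or 8 of 11 other settings, ended that call. Endothelial cells had -0.255 (12 of 13 lower; adjusted p = 0.0125), and -0.208 without AIA-cold-WTD replicate 1 or -0.129 without AIA-hot replicate 2, neither passing. Adipocytes had -1.333 (12 of 14 lower; adjusted p = 0.000417) and erythroid cells -1.6 (9 of 9 lower; adjusted p = 0.00383). Without AIA-cold-WTD replicate 1 these were -0.465 and -0.384 and did not pass. With slide as a fixed block they were -2.255 and -2.459. In that fit the cold part rests on AIA-cold-WTD replicate 1 alone and the hot part on AIA-hot replicate 3. The values therefore carry the array whose loss ended both calls and add no support.

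The first pattern weighed is that 75 genes were called lower than control in AIA-cold or AIA-hot, while the controls shared slide 1 with a single arthritic array. The dim control replicate 1 as a source cannot be judged from these genes. Without it their median change kept 89.7% of its size (-1.37 against -1.53), but they were chosen with that array in the fit. A gene resting on it alone would have had a wide spread and would rarely have been called. Without it 29 of the 126 calls in AIA-cold and 5 of the 13 in AIA-hot remained. A slide 1 effect as the whole fall stays open. The median of AIA replicates 2 and 3 less the controls was -0.58, which is 54.1% of that of the 6 arrays with WTD (-1.08). Neither set of arrays was in the comparisons that chose the genes, but the controls subtracted from both were. Genes chosen for high control values would leave any array below the controls, so this ratio cannot decide. AIA replicate 1, on slide 1, lay at -0.66. An earlier form that set it against replicates 2 and 3 (113%) would have counted against a slide effect as the whole fall. A smaller slide effect stays open too, because AIA replicate 1 lay above both other AIA arrays in 40% of these genes against 29.9% of all genes. An effect of the cold and hot models themselves, the biological difference in the design, was not tested apart from the slide.

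The second pattern is the low fatty acid and triglyceride synthesis list in AIA-cold against AIA, with a median of -1.09. The list also lay lower in AIA-hot against AIA, at -1.231 (-0.706 without AIA replicate 1), with the AIA-hot arrays on slides 2 and 3. A fall against AIA is therefore not particular to AIA-cold or to slide 4. Less fat in the tissue pieces is argued against as the source in AIA-cold, since the 14 adipocyte genes had a median of -0.26. That lies close to the limit set for this reading after the results were seen. In AIA-hot against AIA the adipocyte list lay lower too (-0.846). A slide 4 effect stays open, because its 2 readings disagree: AIA-cold-WTD replicate 1, on the same slide, lay -1.41 from the AIA-cold mean of 2.79 ± 0.41 (SD, n = 3) where replicates 2 and 3, on slide 5, lay 1.34 above it, but after the adipocyte mean was subtracted it lay 1.11 above AIA-cold and they 0.87. The plain reading alone was used at first and would have counted for the slide. The title of replicate 1 carries the letter G and those of replicates 2 and 3 the letter Z, so slide and letter cannot be told apart. The cold model as a biological source remains untested apart from slide 4.

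The third pattern is high Alox15b and Zim1 in AIA-cold and not in AIA-hot or AIA-cold-WTD. Skin in the tissue pieces stays open: the 4 measured keratinocyte genes had a median difference of 0.14 between AIA-cold and AIA-hot, first read as counting against it, but their mean lay only 1.05 (AIA-cold) and 0.41 (AIA-hot) above the lowest signal well above background. The epithelial genes Tgm1 and Gsdma lay at -1.83 and -2.47 in AIA-cold against -2.84 and -3.82 in AIA-hot. A slide 4 effect is open because only 1 other array shared that slide: AIA-cold-WTD replicate 1 lay at -4.46 SD (Zim1) from the AIA-cold mean and was not well above background for Alox15b, which was read as counting against the slide before that limit was applied. That array also carries the title letter G and the other AIA-cold-WTD arrays the letter Z, so slide and letter cannot be told apart. The rise against AIA-hot and the fall with WTD share the same AIA-cold arrays, so high values on those alone would give both. A response to the cold model that WTD may lower is therefore a hypothesis. Skin, the shared arrays and the single other array of slide 4 leave it unsettled.

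Other splits of the 6 arrays of a comparison were refitted in the same way. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. AIA-cold against control gave 126 calls in the real split, reached by 1 of 10, and at most 0 in another. AIA-hot against control gave 13, reached by 2 of 10, and a highest other of 16, with AIA-hot replicates 1 and 2 and control replicate 1 on one side; slide as a fixed block gave 5. AIA-cold against AIA-hot and AIA-cold-WTD against AIA-cold each gave 2, reached by 1 of 10, and at most 0 in another. AIA against control, AIA-cold against AIA and AIA-hot against AIA gave 0, as did all 10 splits, and AIA-hot-WTD against AIA-hot gave 0 with a highest other of 2. For the difference of WTD effects and for the genes common to the 3 comparisons with control, 100 splits were drawn, with a real count of 0 and a highest other of 1 and 0. Any split reaches a count of 0, so for these 6 results the splits say nothing about chance.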

How the results depend on the processing

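The alternatives were planned except 3 chosen after the array intensities were seen: array weights, the fit without the dim control array in comparisons that do not hold it, and score genes chosen without it. No paired analysis was possible because the replicate numbers follow accession order and pair no arrays. A fixed block for slide gave no value for AIA-cold against control, AIA or AIA-hot or for genes common to the 3 comparisons with control. For AIA and AIA-hot against control it rests on AIA replicate 1. For WTD it rests on AIA-cold-WTD replicate 1 in the cold model and AIA-hot replicate 3 in the hot. Slide and group overlap by design; for every other change below the cause was not tested, except that fewer arrays or genes enter some fits.

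Counts of called genes for AIA-cold against control (126) were 203 with normexp (78 higher, 125 lower), 222 after quantile normalization (130 and 92), 227 in the series table (133 and 94), 206 with no filter (46 and 160), 69 with the muscle covariate (25 and 44), 0 with slide as a random block, and 0 with only these groups in the fit. Of the 126, 67 were also called with normexp, 104 after quantile normalization and in the series table, 106 with no filter and 55 with the muscle covariate. AIA-hot against control (13) gave 0 with normexp, 22 after quantile normalization and in the series table (8 and 14 each, 11 shared), 3 with no filter, 6 with probes above background on all arrays, 0 with slide as a random block, 5 as a fixed block (0 shared), 0 with the muscle covariate and 0 with only these groups. AIA against control (0) gave 13 with slide fixed (4 and 9). AIA-cold against AIA (0) gave 15 after quantile normalization and in the series table, 2 with the muscle covariate and 28 with only these groups (15 and 13). AIA-hot against AIA (0) gave 2 after quantile normalization, 1 in the series table, 142 with slide fixed (122 and 20) and 1 with only these groups. AIA-cold against AIA-hot (2) gave 0 with normexp, with no filter, with probes above background on all arrays, with slide as a random block and with only these groups. AIA-cold-WTD against AIA-cold (2) gave 0 with normexp, with probes above background on all arrays and with only these groups, 4 after quantile normalization and in the series table, and 32 with slide fixed (15 and 17). AIA-hot-WTD against AIA-hot (0) gave 6 with slide fixed (1 and 5). The difference of WTD effects (0) gave 3 after quantile normalization and in the series table, 5 with slide fixed, 1 with the muscle covariate and 2 with only these groups.

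Without the dim array, AIA-cold against AIA gave 76, AIA-cold against AIA-hot 5, AIA-cold-WTD against AIA-cold 8, AIA-hot-WTD against AIA-hot 1 and the difference of WTD effects 2. Array weights gave 34 for AIA, 6221 for AIA-cold and 4073 for AIA-hot against control, 1157 for AIA-cold and 262 for AIA-hot against AIA, 3866 for AIA-cold against AIA-hot, 4281 and 1 for WTD in the cold and hot models, 1394 for their difference and 24 for the common genes. The weights ran from 0.0874 (control replicate 1) to 5.15. Refitted on 23558 genes with weights, AIA-cold against control gave 6203 calls, and a split with AIA-cold replicates 1 and 3 beside control replicate 1 gave 5915, which points to a structure of the arrays, so these counts are not read as effects.

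Leaving out 1 array gave 0 to 9 calls for AIA against control (highest without control replicate 3), 0 (without AIA-cold replicate 2) to 297 (without control replicate 2) for AIA-cold against control, and 0 (without AIA-hot replicate 2) to 61 (without AIA-hot replicate 3) for AIA-hot against control. It gave 0 to 4 for AIA-cold against AIA, 0 to 3 for AIA-hot against AIA, 0 to 2 for AIA-cold against AIA-hot, 1 to 82 (without AIA-cold-WTD replicate 1) for AIA-cold-WTD against AIA-cold, 0 to 0 for AIA-hot-WTD against AIA-hot, 0 to 9 (without AIA-cold-WTD replicate 1) for the difference and 0 to 8 (without control replicate 3) for the common genes. The arthritis score difference ran from -0.25 to -0.055 (without AIA-cold-WTD replicate 1) for WTD in the cold model, -0.021 (without AIA-hot-WTD replicate 1) to 0.194 in the hot model and -0.048 (without AIA-hot replicate 2) to 0.158 between AIA-cold and AIA-hot. The last was 0.233 with normexp, 0.244 with probes above background on all arrays and -0.008 with score genes chosen without control replicate 1.

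The 94 calls of lists all ended with an estimated correlation; fry called 0 lists moving one way, and 7 changing in either direction, the lowest adjusted p being 0.000479 for the glucocorticoid response in AIA-cold against control. With the preset correlation 85 calls held after quantile normalization, 71 with normexp, 77 with slide as a random block, 41 with it fixed (13 ended and 10 turned), and in 428 of the fits without 1 array (170 ended and 8 turned). Lists whose direction turned had these medians. Against control, chemokines in AIA were at 0.008 with probes above background on all arrays (the test turned, the median did not) and skeletal muscle in AIA at -0.009 with its own mean as covariate, which removes it by construction. B and plasma cells in AIA-hot were at -0.221 with normexp. Slide fixed gave glycolysis 0.196 and cholesterol synthesis -0.042 in AIA-hot against control (the latter by its test alone), glycolysis -0.07 and cholesterol synthesis -0.205 for WTD in the cold model, and for WTD in the hot model collagens 0.423, fatty acid oxidation -0.194, oxidative phosphorylation -0.138, brown fat -0.005, fatty acid synthesis -0.201 and adipocytes -0.354.

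Leave-one-out ranges of lists that turned were -0.531 to 0.038 for angiogenesis and -0.511 to 0.187 for endothelial cells in AIA against control (highest without control replicate 1), and -0.031 (without AIA-hot replicate 2) to 0.985 for interferon in AIA-hot against AIA. Adipocytes for WTD in the cold model ran from -1.081 to 0.261 (without AIA-cold-WTD replicate 1). For WTD in the hot model, interferon ran from -0.851 to 0.157 (without AIA-hot replicate 2; 0.02 without AIA-hot-WTD replicate 2), cell cycle from -0.243 (without AIA-hot replicate 3) to 0.628 and skeletal muscle from -0.558 (without AIA-hot-WTD replicate 3) to 2.238. Of the 38 calls of named genes 35 held after quantile normalization and in the series table, 36 with the mean of probes, 27 with no filter, 16 with normexp, 16 with the muscle covariate, 1 with slide as a random block and 0 with only the groups compared. Signal limits dim genes most: 43.3% of probes were well above background on control replicate 1.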

Other observations

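The heat shock and cold-sensing lists were not called in any of the 9 comparisons. Heat shock proteins (14 genes) had a median log2 difference of -0.12 between AIA-cold and AIA-hot (adjusted p = 0.215) and 0.21 between AIA-hot and AIA (adjusted p = 0.0943). The cold-inducible and cold-sensing list, of which 4 genes were measured, had 0.23 between AIA-cold and AIA-hot (adjusted p = 0.305), with the cold-inducible RNA-binding gene Rbm3 at 0.49 (adjusted p = 0.781) and Cirbp at 0.28 (adjusted p = 0.979). Pain mediators and receptors (9 genes) ranged over the 9 comparisons from -0.14 to 0.23 and osteoclasts (6 genes) from -0.09 to 0.21, with no call. Synovial lining genes lay lower in AIA-cold than in AIA-hot in 9 of 10 genes (-0.34; adjusted p = 0.0526) and did not pass. Cyp2e1, an oxidase of small molecules and fatty acids named after its value was seen, was at 3.56 in AIA-cold against control (adjusted p = 0.0594) and passed when adjusted over the xenobiotic list alone.

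Markers of blood and bone varied between single arrays. The mean of 9 neutrophil genes was 2.17 on AIA-cold-WTD replicate 3 and 2.09 on AIA-hot-WTD replicate 2, against -1.34, -0.89 and -1.46 on the controls, and the mean of 9 erythroid genes was 2.72 and 3.14 on the same 2 arrays. The mean of 9 osteoblast and bone genes was 1.77 on AIA-cold replicate 3, 1.68 on AIA-hot-WTD replicate 2 and 1.52 on control replicate 1, against -1.94 and -2.18 on the other AIA-cold arrays and -2.05 and -1.07 on the other controls. These values were picked out after they were seen and no test was run on them.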
